A study of Caenorhabditis elegans with 4 samples.

How the data were processed

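Whole adult hermaphrodites of C. elegans were lysed, V5-tagged PRG-1 was immunoprecipitated, and the small RNAs in the precipitate were sequenced at a commercial facility, per the labels' protocols. There were 4 libraries in 2 groups, wild type and prg-1 lacking the PAZ domain, with 2 libraries each, and groups and replicate numbers were taken from the sample titles. No input RNA, untagged control precipitate or PRG-1 protein level was analysed here.

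The authors deposited raw counts of reads per piRNA, in sense and antisense orientation, for 15913 piRNAs of a piRNAdb set for C. elegans (version 1.7.6), per the file headers. The authors also deposited raw counts of reads per 1 Mb bin and strand of the ce11 genome, in 104 bins, per the file headers. Another deposited table by the authors gave the total reads, genome-mapped reads and piRNA reads of each library, and piRNA reads per 1000000 genome-mapped reads. The piRNA reads of that table equalled the sum of the sense counts, and its genome-mapped reads equalled the sum of both strands over all bins. The aligner, adapter trimming, mismatch allowance, length selection and treatment of reads with several matches are not given in the sources used here. If reads with several matches were counted more than once or assigned at random, piRNAs with near-identical sequences, and fragments of abundant RNAs that match a piRNA, would be affected, so single piRNAs that share sequence are uncertain. The table of piRNAs gives identifiers with neither sequence nor position, so 21UR names, coordinates, lengths and first nucleotides were not used here.

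Genome bins were annotated with Ensembl release 115 of WBcel235, the same assembly as ce11, whose chromosome lengths match the number of bins per chromosome. A strand-specific bin counted as rich in piRNA genes with at least 100 annotated ones. The plus-strand bin of chromosome I that starts at 15 Mb holds 4 annotated genes of the small and large subunit ribosomal RNAs and is called the ribosomal RNA bin; the 5S genes, 15 of which lie in 1 bin of chromosome V, and the mitochondrial ribosomal RNA genes lie in other bins.

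Total piRNA abundance was the sum of sense counts per 1000000 genome-mapped reads, the scaling that the design text of the series names. Groups were compared by mean and SD and by a two-sided exact permutation test over 6 arrangements, whose smallest p is 0.33. Single piRNAs were tested with edgeR 4.0.16 (quasi-likelihood fit and test, R 4.3.3) on the deposited sense counts, in a pair of fits. In one fit the library size was the number of genome-mapped reads without further scaling, and in the other it was the number of piRNA reads with TMM factors. Low counts were removed with the defaults of filterByExpr (a minimum count of 10 and a minimum total of 15), and p-values were adjusted by Benjamini and Hochberg with a threshold of 0.05. Of the 15913 piRNAs, 6251 had at least 1 sense read, and 1355 and 1172 entered the fits. In each library the tested piRNAs held at least 81.6% and 81.9% of the piRNA reads. Strand-specific bins were tested with edgeR in the same way. The SE of a log2 fold change was its absolute value divided by the square root of the edgeR F statistic. Such an SE is approximate, above all where a genotype had few reads. Libraries were thinned to 17197 piRNA reads, the depth of the shallowest, over 100 seeded draws. A count of 0 allows up to 3 reads, which corresponds to 0.208 to 0.464 reads per 1000000 genome-mapped reads over the libraries. Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9 were used for the remaining steps.

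Both edgeR fits were tested on simulated counts with 200 changed piRNAs, 25 per fold size, drawn with the spread of each fit. A first simulation, with a single spread for both fits and only the smaller fold sizes, recovered none of its changed piRNAs, after which each fit's own spread and larger fold sizes were used. Scaled to genome-mapped reads (1648 piRNAs in the step), 83.3% of tested piRNAs with a log2 change of -6 were recovered, 45.5% at -4, 4.76% at -3 and 0% at -2. In the upward direction 100% were recovered at 6, 36% at 4, 8% at 3 and 8% at 2, and 0 of 1462 unchanged piRNAs were called. Within the pool (1093 piRNAs in the step), 96% were recovered at -6, 76% at -4, 60% at -3, 43.5% at -2, 52% at 2 and 96% at 3, and 8 of 895 unchanged piRNAs were called. Increases of 4 or less on the log2 scale per genome-mapped read were thus mostly missed in the simulation. It changed 200 piRNAs, whereas most tested piRNAs were called in the data, so its threshold on the unadjusted p was stricter. It also drew each piRNA independently. Its recovery rates therefore do not give the power in the data, and a count of 0 higher piRNAs was not shown to exclude such increases.

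The comparisons, their tests, the rule for named piRNAs and a list of alternatives were chosen before the data were examined. The rule named, for each fit and direction, up to 6 piRNAs with the steepest change among those past the threshold, with a mean of at least 100 reads and both mutant values beyond both wild type values, plus the 10 piRNAs with the highest mean. It gave 16 piRNAs. The alternatives chosen then were DESeq2 1.42.0, other filters on low counts, other size factors, other denominators, the replicate number as a block and leaving out each library. Alternatives without the ribosomal RNA bin, without cel-piR-8767 and with other bins as the denominator, and the comparison of strand-specific bins, were added after the data were seen. The labels gave no batches. Dixon's test for outliers was not run, since each group had 2 libraries.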

Results

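Small RNAs bound to the Piwi Argonaute PRG-1 were compared between wild type and prg-1 mutant adult hermaphrodites of the nematode Caenorhabditis elegans grown at 25 °C. PRG-1 carries piRNAs, short germline RNAs that guide the recognition of target transcripts. The mutant protein lacked the PAZ domain, the part of an Argonaute that holds the 3' end of its small RNA. Both forms of the protein carried a V5 tag and were immunoprecipitated from lysates of whole animals, and the co-purified small RNAs were sequenced. Each genotype had 2 libraries. Wild type replicates 1 and 2 held 7359005 and 9451085 reads, of which 6461936 and 8416474 mapped to the genome. Mutant replicates 1 and 2 held 9015827 and 16226223 reads, of which 7819170 and 14430880 mapped to the genome. The labels did not say whether replicates came from separate cultures, so p-values measure only the spread between these samples, which may be technical.

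The first comparison asked how much piRNA was bound to PRG-1 in each genotype. Sense piRNA reads were at 19358 ± 3832 per 1000000 genome-mapped reads (RPM) in wild type and at 1896 ± 996 in the mutant (mean ± SD, n = 2 each). The mutant mean was 9.79% of the wild type mean, with an SD of 5.14 percentage points over the mutant libraries. Wild type replicates 1 and 2 gave 22068 and 16648 RPM, and mutant replicates 1 and 2 gave 2600 and 1192. These values rested on 142604 and 140121 piRNA reads in wild type and on 20327 and 17197 in the mutant. Each wild type library exceeded each mutant library, by 6.40-fold for the closest pair and by 18.5-fold for the most distant pair. An exact two-sided permutation test on the log2 values gave p = 0.33, the smallest value that 2 against 2 libraries allow, so the design could not reach 0.05. The mutant replicates differed from each other by 2.18-fold and the wild type replicates by 1.33-fold.

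**Figure D1:**
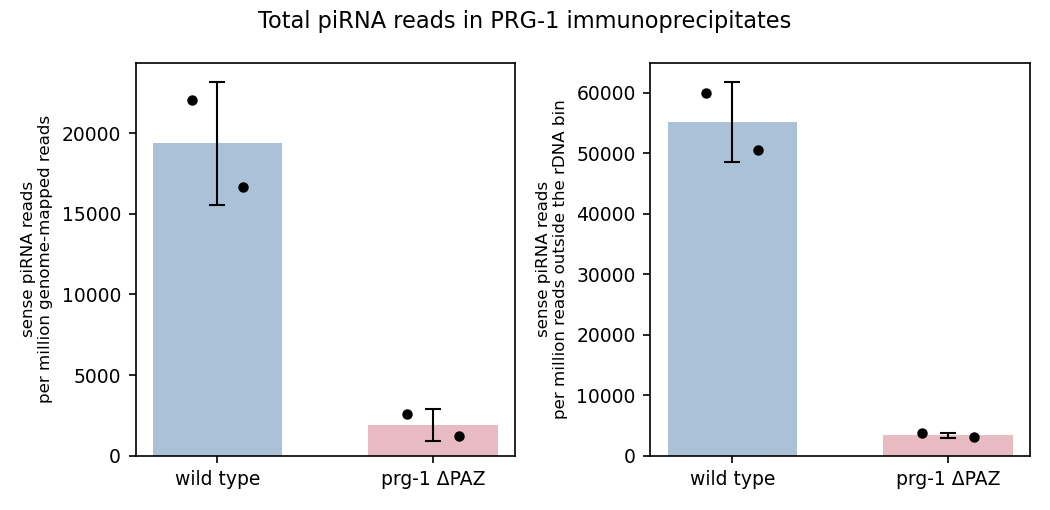
Sense piRNA reads per 1000000 genome-mapped reads (left) and per 1000000 reads outside the 1 Mb bin of chromosome I that holds small and large subunit ribosomal RNA genes (right). Bars are means, error bars are SD and points are the 2 libraries of each genotype; the mutant mean was 9.79% of wild type on the left and 6.12% on the right.

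A bin on the plus strand of chromosome I between 15000001 and 16000000 (WBcel235), which holds small and large subunit ribosomal RNA genes, took a large share of the genome-mapped reads. It held 63.2% and 67.1% of the genome-mapped reads in wild type and 29.6% and 61.2% in mutant replicates 1 and 2. With reads outside this bin as the denominator, a choice made after the data were seen, piRNA reads were at 55266 ± 6602 per 1000000 such reads in wild type and at 3380 ± 441 in the mutant (SD, n = 2 each). The mutant mean was then 6.12% of wild type, and the mutant replicates differed by 1.20-fold. This closeness of the mutant replicates rested on the most abundant piRNA, cel-piR-8767. Without it, mutant replicates 1 and 2 were at 3432 and 1505 on this denominator, 2.28-fold apart, and the mutant mean was 4.61% of wild type.

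Individual piRNAs were compared next, with genome-mapped reads as the library size. Of 1355 piRNAs with enough reads to test, 1042 were lower in the mutant and 0 were higher (edgeR quasi-likelihood test, adjusted p under 0.05). At an unadjusted p under 0.05 the counts were 1081 lower and 0 higher, and DESeq2 called 1043 lower and 0 higher. The median log2 fold change was -4.03, with quartiles of -5.40 and -2.96. For 137 of the 1355 piRNAs neither mutant library held a read. With reads pooled by genotype, and any pooled count under 3 reads raised to a floor of 3, the median log2 ratio was -3.95. Both mutant values lay below both wild type values for 1278 of the 1355 piRNAs. The 16.7% that chance gives for a single piRNA is no reference for this share. The piRNAs share the same 4 libraries and the lower total, so they are not independent. The number of calls moved strongly with the library left out. With 1 library left in a genotype, the spread came only from the 2 libraries of the other genotype. The calls were lost without either wild type library, where the spread came from the mutant libraries alone. The median log2 fold change was -3.61 without wild type replicate 1, -4.01 without wild type replicate 2, -5.85 without mutant replicate 1 and -3.22 without mutant replicate 2, over 1384, 1456, 1821 and 1788 tested piRNAs. With reads outside the ribosomal RNA bin as the library size, 1569 of 1619 piRNAs were lower.

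Among piRNAs with a mean of at least 100 reads, 6 had the steepest decreases. The piRNA cel-piR-7426 had 450 and 381 reads in wild type and 2 and 1 in the mutant, a wild type to mutant ratio of 414 with a 95% counting interval of 141 to 2013. Its log2 fold change was -8.48 ± 1.84 (SE), with an edgeR adjusted p of 1.37e-04. For cel-piR-5963 the reads were 725 and 787 against 3 and 3, a ratio of 377 (counting interval 173 to 1029). The reads of cel-piR-10491 were 545 and 381 against 4 and 0, and those of cel-piR-4012 were 234 and 363 against 2 and 1. The piRNA cel-piR-3490 had 590 and 567 reads in wild type and 5 and 1 in the mutant. The more abundant cel-piR-2195 went from 351 ± 16.3 to 1.42 ± 1.61 RPM (SD, n = 2 each), a ratio of 327 (counting interval 220 to 511). These 6 piRNAs had log2 fold changes between -8.48 and -7.88 and edgeR adjusted p values up to 6.04e-04. Their calls were lost without either wild type library, at log2 fold changes of -8.72 to -7.53. Counting intervals were computed on reads pooled by genotype and cover counting error only, since reads amplified by PCR are not independent molecules.

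Of the 10 piRNAs with the most reads over the 4 libraries, 7 were lower in the mutant at an edgeR adjusted p under 0.05. The piRNA cel-piR-10604 fell from 470 ± 82.7 to 2.22 ± 2.65 RPM, cel-piR-8559 from 363 ± 41.9 to 6.40 ± 5.23, and cel-piR-10993 from 252 ± 9.91 to 1.59 ± 1.37 (SD, n = 2 each). Smaller decreases were measured for cel-piR-9847, which fell from 181 ± 26.2 to 9.87 ± 8.28 RPM (log2 fold change -4.20 ± 1.54 SE, edgeR adjusted p = 0.0138). The remaining piRNAs of the 7 were cel-piR-2195, cel-piR-5915 and cel-piR-3719. The calls of these 7 were also lost without either wild type library. The other 3 of the 10 did not pass the threshold. The piRNA cel-piR-9221 had 181 ± 62.1 RPM in wild type and 29.2 ± 28.6 in the mutant, with an edgeR adjusted p of 0.0850; it was lower past the threshold by DESeq2, with the library size outside the ribosomal RNA bin, and without either mutant library. For cel-piR-14009 the levels were 83.2 ± 40.0 and 86.5 ± 63.6 RPM, with an edgeR adjusted p of 0.968. The most abundant piRNA, cel-piR-8767, was at 604 ± 267 RPM in wild type and 395 ± 300 in the mutant, with an edgeR adjusted p of 0.705, and it was lower past the threshold without mutant replicate 2 (log2 fold change -1.72), while its log2 fold change was 0.0084 without mutant replicate 1. It made up 3.59% and 2.49% of the piRNA reads in wild type replicates 1 and 2, 7.05% in mutant replicate 1 and 51.0% in mutant replicate 2.

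**Figure D2:**
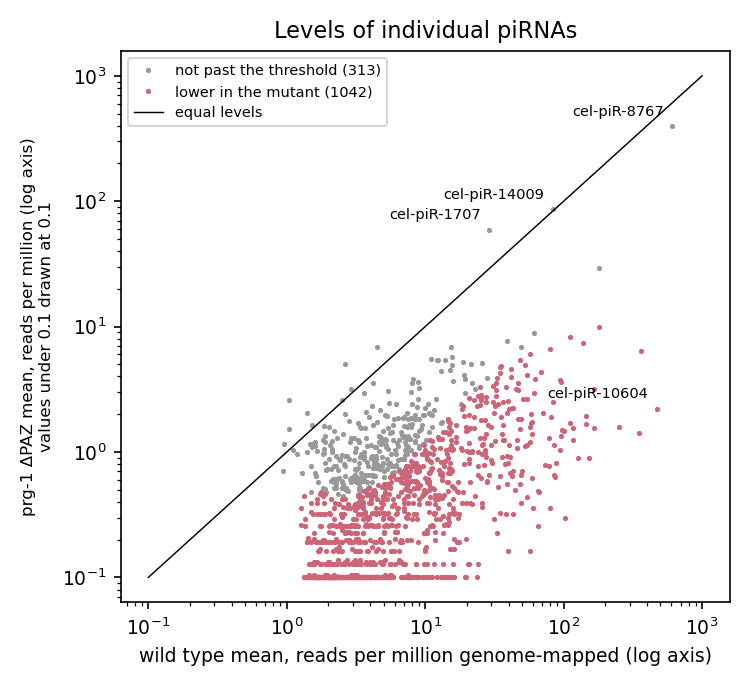
Mean RPM of each of the 1355 tested piRNAs in wild type (horizontal log axis) and in the mutant (vertical log axis), with the line of equal levels; values under 0.1 are drawn at 0.1. The 1042 piRNAs lower in the mutant are in red, and cel-piR-8767, cel-piR-14009 and cel-piR-1707 lie near the line of equal levels.

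To ask which piRNAs changed relative to the others, the counts were also scaled within the piRNA pool. Of 1172 piRNAs tested, 186 were lower and 96 were higher relative to the pool, and 890 did not pass the threshold (edgeR adjusted p under 0.05). The lower piRNAs kept a median of 0.938% of their wild type level per genome-mapped read, and the higher piRNAs kept a median of 58.8%. The filter let rare piRNAs enter through their mutant reads, which tilts the 58.8% upward. Of the 96 that were higher in the pool, 65 were also tested per genome-mapped read, and 0 of those 65 were lower and 0 were higher there. DESeq2 called 101 lower and 66 higher within the pool. Without a filter on low counts 213 of 6251 were lower and 32 higher, and without TMM 139 and 54 of 1172. The piRNAs tested within the pool numbered 633 and 646 without wild type replicates 1 and 2, and 1769 and 1847 without mutant replicates 1 and 2. Their median log2 fold changes were -0.07, -0.11, -1.31 and -0.58. Counts of calls over such unlike sets are not comparable.

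Among piRNAs with a mean of at least 100 reads, cel-piR-7426, cel-piR-5963, cel-piR-10491, cel-piR-2195, cel-piR-4012 and cel-piR-10604 had the steepest decreases within the pool, with log2 fold changes from -5.05 to -4.60 and edgeR adjusted p values up to 4.67e-06. In the other direction, 3 piRNAs met the criteria for being named. The piRNA cel-piR-1707 rose within the pool by a log2 fold change of 4.55 ± 0.81 (SE), with an edgeR adjusted p of 2.21e-06. It had 189 and 244 reads in wild type and 664 and 487 in the mutant, which made 29.1 ± 0.182 and 59.3 ± 36.2 RPM (SD, n = 2 each). Scaled to genome-mapped reads, its log2 fold change was 1.03 ± 1.30 (SE), with an edgeR adjusted p of 0.445, and it passed the threshold as higher only without mutant replicate 2 (log2 fold change 1.54). The piRNA cel-piR-14009 rose within the pool by 3.39 ± 0.83 (log2, SE; edgeR adjusted p = 6.75e-04). The piRNA cel-piR-8767 rose within the pool by 3.83 ± 1.34 (log2, SE; edgeR adjusted p = 0.0246). The size of this rise rested on mutant replicate 2, without which it was 0.89 (edgeR adjusted p = 0.407). The call of cel-piR-8767 was also lost without either wild type library, without TMM, with median-of-ratios size factors and with at least 50 reads required, at log2 fold changes of 3.25 to 4.91, and that of cel-piR-14009 was lost without either wild type library.

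Among the piRNAs that passed the filter on low counts, the change within the pool differed with abundance. Over 5 equal groups of the tested piRNAs, ranked by their mean level from the rarest to the most abundant, the median log2 fold change within the pool was 0.88, -0.06, -0.25, -0.68 and -1.30. The number lower rose from 0 in the rarest group to 103 in the most abundant group, while the number higher was 48 and 11 in these groups. Per genome-mapped read the medians were -4.34, -3.61, -3.63, -3.90 and -4.70. The ranking used the same reads as the fold changes, and the filter on low counts limits which rare piRNAs were tested. Within the pool the filter scaled with piRNA reads, so fewer reads were needed in a mutant library than in a wild type library. Rare piRNAs could thus enter through their mutant reads, which tilts the rarest group toward higher calls. Per genome-mapped read they entered mainly through wild type reads, which tilts it the other way. The calls in the rarest group therefore cannot show an effect of abundance. The medians of the rarer groups moved with the libraries used. Within the pool the rarest group was at -5.44 without mutant replicate 1 and at 2.47 without wild type replicate 1. Without any filter the 5 medians within the pool were -1.76, -2.53, -3.39, -1.06 and -1.36, so the order was not kept. No test was run on these medians.

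The number of different piRNAs and the evenness of the pool were compared at matched depth. After thinning to 17197 piRNA reads, wild type libraries held 2396 ± 134 piRNAs and mutant libraries 2235 ± 435 (SD, n = 2 each; exact permutation p = 1.00). The 100 most abundant piRNAs of each library took 45.6% ± 2.78 of its piRNA reads in wild type and 55.8% ± 21.3 in the mutant (SD, n = 2 each; exact permutation p = 1.00). Both differences were smaller than the spread between the mutant replicates, which held 2542 and 1927 piRNAs, and 40.8% and 70.8% of reads in the top 100. Without cel-piR-8767 both directions turned. At the 8435 reads then left in the shallowest library, the mutant mean was higher by 187 piRNAs, against a difference of -85.3 with cel-piR-8767 at that depth, and the share of the top 100 was 44.1% in wild type and 38.6% in the mutant.

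Chromosome IV carries most piRNA genes of C. elegans, with 14714 of the 15363 annotated ones. Its share of genome-mapped reads was 5.42% ± 0.514 in wild type and 8.67% ± 4.64 in the mutant (SD, n = 2 each; exact permutation p = 0.667, adjusted 0.778 over 7 chromosomes). Mutant replicate 1 had 11.95% and replicate 2 had 5.39%, so the difference was smaller than the spread between mutant libraries. Chromosome X held 2.39% ± 0.147 of the reads in wild type and 4.84% ± 0.429 in the mutant, and mitochondrial DNA held 0.351% ± 0.0867 and 0.853% ± 0.0606 (SD, n = 2 each). For both, each mutant library exceeded each wild type library, with an exact permutation p of 0.33 and an adjusted value of 0.467. With reads outside the ribosomal RNA bin as the denominator, the differences for chromosomes I, III, IV and V changed sign. The log2 differences went from 1.02 to 0.43 for chromosome X, from 1.30 to 0.71 for mitochondrial DNA and from -0.0013 to -0.59 for chromosome II.

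Along chromosome IV, the reads from the piRNA gene cluster between 13 and 18 Mb were lower in the mutant. This comparison of 208 1 Mb bins, split by strand, was chosen after the data were seen. In the 10 strand-specific bins of that cluster, which hold 11574 annotated piRNA genes, 5 were lower per genome-mapped read (edgeR adjusted p = 0.0353 for each) and 6 were lower per read outside the ribosomal RNA bin. On the minus strand between 16000001 and 17000000, with 1512 piRNA genes, reads fell by 2.70 on the log2 scale (SE 0.32), and on the plus strand between 15000001 and 16000000, with 1812 piRNA genes, they fell by 2.62 (SE 0.28). The 6 bins of the second cluster, between 4 and 7 Mb, hold 2827 annotated piRNA genes, and 0 of them were lower by edgeR under either scaling. Strand-specific bins with miRNA genes took many of the reads in both clusters. Reads from 13 to 18 Mb were at 44.8% of wild type in the mutant, and at 20.8% without the bin that holds mir-52. Reads from 4 to 7 Mb were at 177% of wild type, and at 85.8% without the bin that holds mir-228. The other bins between 4 and 7 Mb held 459 to 1174 reads per 1000000 genome-mapped reads in wild type. Bins with few piRNA genes held similar levels, such as 958 and 1035 on the plus strand of chromosome I from 1 to 1000000, with 3 piRNA genes. A fall of the piRNAs between 4 and 7 Mb could therefore go unseen in these bins. The 73 bins with few piRNA genes and no miRNA or ribosomal RNA gene had a median log2 fold change of -0.15 per genome-mapped read and -0.66 per read outside the ribosomal RNA bin. Reads of a 1 Mb bin cannot be assigned to a single gene.

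**Figure D3:**
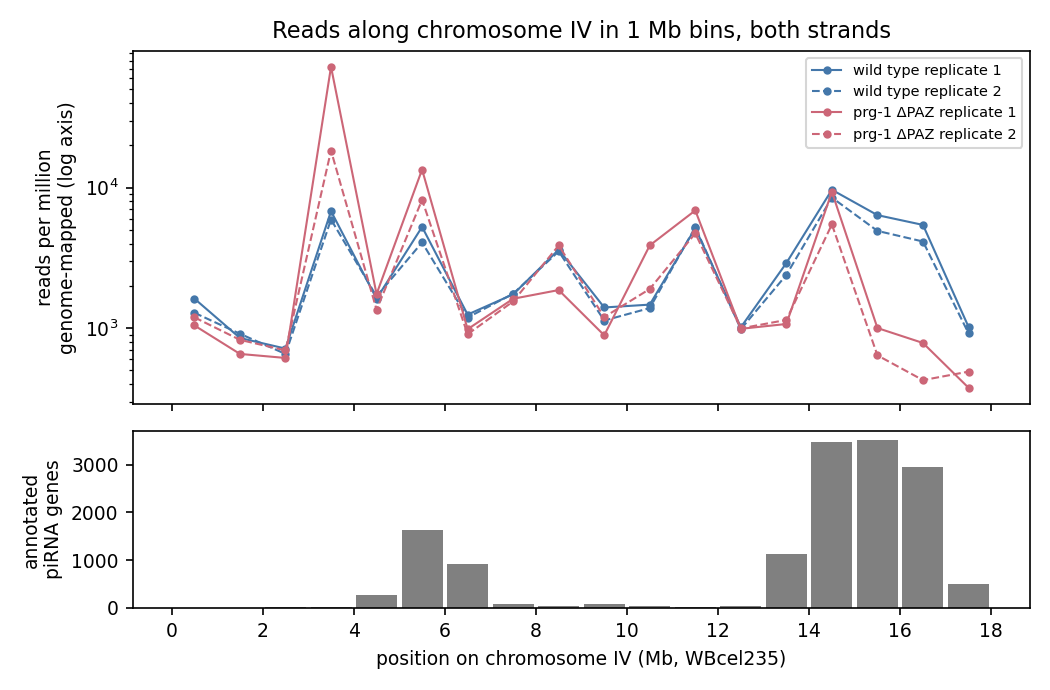
Reads per 1000000 genome-mapped reads in 1 Mb bins along chromosome IV (top, log axis, both strands, 1 line per library) and the number of annotated piRNA genes in each bin (bottom). Between 13 and 18 Mb the mutant libraries lay below the wild type libraries in most bins, and the bin from 3 to 4 Mb, which holds mir-58a, was higher in both mutant libraries.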

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

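All tests in this part were chosen only after the results were seen. Antisense reads, which the comparisons of piRNA levels did not use, were higher in both mutant libraries than in both wild type libraries for cel-piR-14284. It had 8 and 15 antisense reads in mutant replicates 1 and 2, against 5 and 6 in wild type, and 0 sense reads in the 4 libraries. The mutant mean was 1.03 antisense reads per 1000000 genome-mapped reads. With so few reads, and with one such piRNA picked out of the whole table, no explanation was weighed.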

How the results depend on the processing

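The alternatives without the ribosomal RNA bin, without cel-piR-8767 and with other bins as the denominator were chosen only after the results were seen. Total piRNA reads were lower in the mutant under each alternative run, with log2 differences from -4.55 to -2.88. Among the values of named piRNAs under alternatives, 254 kept direction and side of the threshold, 36 lost the threshold, 6 newly passed it and 8 reversed, none of the 8 past the threshold in either setting. Per genome-mapped read, the log2 fold change of cel-piR-14009 was -0.73 with the library size outside the ribosomal RNA bin, -0.082 with the replicate number as a block and -1.0 to 0.66 when leaving out a library, and that of cel-piR-8767 was -1.72 to 0.0084 when leaving out a library. Within the pool, cel-piR-9221 was at -0.34 without a filter and at -0.0016 to 1.32 when leaving out a library, and cel-piR-9847 was at 0.13 with at least 50 reads.

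Per genome-mapped read, piRNAs lower in the mutant numbered 386 of 439 with at least 50 reads in 2 libraries (fewer piRNAs tested), 1569 with the library size outside the ribosomal RNA bin, and 0 to 1696 when leaving out a library. The 0 came from leaving out either wild type library. Higher piRNAs numbered 1 without a filter and 0 to 2 when leaving out a library. Within the pool, lower piRNAs numbered 101 by DESeq2, 75 with at least 50 reads (fewer tested) and 56 to 188 when leaving out a library. Higher piRNAs numbered 32 without a filter, 53 with at least 50 reads, 54 without TMM and 23 to 106 when leaving out a library. Leaving out a library changed the number tested within the pool to between 633 and 1847. Replicate numbers were not treated as pairs in the main fits. Deviations of same-numbered libraries correlated across piRNAs at 0.116 per genome-mapped read and -0.00770 within the pool, over 2 pairs. Such a correlation cannot show whether same-numbered libraries were prepared together. With the number as a block, 782 were lower per genome-mapped read, and 123 lower and 54 higher within the pool, where cel-piR-8767 lost its call (log2 fold change 2.88, edgeR adjusted p = 0.419).

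Median log2 changes per genome-mapped read in the rarest group were -2.54 without a filter, -3.67 with at least 50 reads and -6.41 to -3.24 when leaving out a library. Leaving out a library gave the second group a range of -7.03 to -3.12 and the middle group -5.08 to -2.99. Within the pool, the medians without a filter were -1.76, -2.53 and -3.39 in the 3 rarest groups. Leaving out a library gave -5.44 to 2.47 in the rarest group and -6.08 to 0.68 in the next.

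Without cel-piR-8767 the mutant mean was higher by 187 detected piRNAs, and the difference in the top 100 share was -5.51 percentage points. Leaving out a library gave -469 to 146 detected piRNAs and -4.83 to 25.2 points. With reads outside the ribosomal RNA bin, the log2 difference was 0.11 for chromosome I, -0.59 for II, -0.10 for III, -0.018 for IV and -0.12 for V. Chromosome II gave 0.0060 without mitochondrial DNA and -0.18 to 0.18 when leaving out a library, and chromosome IV gave -0.0055 to 1.14. The cause was not tested for these shifts, except where fewer piRNAs were tested. A lone library left in a group was assumed to vary like the other group. Few reads limited the mutant: 17197 piRNA reads in the shallower library.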

Other observations

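The comparisons of bins and antisense reads and the tests of explanations in this part were chosen only after the results were seen, while the calls within the piRNA pool and the medians by abundance were not. Strand-specific bins that hold miRNA genes took another part of the reads, which cannot be assigned to single genes. Per read outside the ribosomal RNA bin, the plus strand of chromosome IV between 3000001 and 4000000, which holds mir-58a, a member of the bantam-related mir-58 family, was higher in the mutant by 2.14 on the log2 scale (SE 0.51, edgeR adjusted p = 9.24e-04). Its reads were 40788 and 45766 in wild type and 563150 and 258159 in the mutant. On the same scale, the minus strand of chromosome V between 6000001 and 7000000, which holds mir-70 and mir-256, was higher by 1.57 (SE 0.50, edgeR adjusted p = 0.0466). The plus strand of chromosome II between 11000001 and 12000000, which holds the mir-35 to mir-44 genes, known as maternal and embryonic miRNAs, fell by 2.30 (SE 0.51, edgeR adjusted p = 2.52e-04). The bins with few piRNA genes and no miRNA or ribosomal RNA gene had a median of -0.66 on this scale. Per genome-mapped read the log2 fold changes of these 3 bins were 2.94, 2.26 and -1.57. None of the 3 passed the threshold there, with edgeR adjusted p values of 0.144, 0.114 and 0.231.

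Antisense reads were few. They were at 134 ± 32.4 per 1000000 genome-mapped reads in wild type and at 35.1 ± 6.05 in the mutant (SD, n = 2 each; exact permutation p = 0.33, the smallest possible). Much of this difference came from cel-piR-10337, with 583 and 573 antisense reads in wild type, 26 and 12 in the mutant and 0 sense reads in the 4 libraries. Without cel-piR-10337 the levels were 54.6 ± 16.7 and 33.0 ± 4.29, so the mutant mean was 60.5% of wild type. Across the 1355 tested piRNAs, the rank correlation of levels was 0.832 between the wild type libraries, 0.645 between the mutant libraries and 0.416 to 0.508 between genotypes. These correlations are across piRNAs, which are not independent replicates.

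Total piRNA reads were lower in the mutant. Dilution by the ribosomal RNA bin was argued against, since it took 29.6% and 61.2% of the mutant libraries and 63.2% and 67.1% of the wild type libraries. Leaving it out could thus only lower the mutant further relative to wild type. The mutant mean was 6.12% of wild type per read outside that bin, with no overlap of the libraries. Dilution by miRNA and ribosomal RNA loci together was argued against as well, at 11.9% ± 8.29 of wild type (SD, n = 2) per read of bins with neither and with few piRNA genes, where the mutant replicates differed by 2.94-fold and the closest wild type and mutant libraries by 4.93-fold. Less PRG-1 protein or a weaker pull-down in the mutant stays open, because neither was measured here. Of 282 piRNAs called relative to the rest of the pool, 96 were higher. Rare ones could enter through their mutant reads, so not all of the 96 count against a single factor for all piRNAs. Such a factor would not give the 103 lower calls in the most abundant group. A lower yield over a background that differs between piRNAs could give them. Weaker binding of piRNAs by the protein without its PAZ domain, the difference the design names, also stays open and may act together with a lower yield.

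The piRNA cel-piR-8767 stayed high in mutant replicate 2, at 607 reads per 1000000 genome-mapped reads against 792 and 415 in wild type and 183 in mutant replicate 1, so this pattern rests on 1 library. It did not account for the lower total, as the mutant mean was 8.0% of wild type without it. A candidate explanation is that fragments of ribosomal RNA were counted as this piRNA. Its reads per read of the ribosomal RNA bin differed by 2.03-fold between the highest and the lowest of the 4 libraries, and those extremes were the wild type libraries, so the spread within wild type leaves this open. Its sequence was not used here, and no biological explanation was tested.

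The piRNAs other than cel-piR-8767 with at least 10 reads in wild type replicate 1 were ranked by that library. Their mutant levels were compared with wild type replicate 2. The lowest-ranked group kept 22.9% and the highest-ranked 10.3% of the wild type level in mutant replicate 1. In mutant replicate 2 they kept 5.54% and 2.55%. With cel-piR-8767 the highest-ranked group kept 11.5% and 7.87%, so the direction turned in mutant replicate 2, and the fitted medians per genome-mapped read did not keep this order in every setting (-4.35 in the middle and -3.93 in the most abundant group without a filter, and -6.41 and -7.03 in the rarest groups and -6.10 in the most abundant without mutant replicate 1). Without cel-piR-8767 the ratios of the shares were 2.23 and 2.18. The bootstrap intervals of the lowest-ranked and highest-ranked groups did not overlap in either mutant library. This argues against ranking on the same noisy counts as the whole cause for these piRNAs. These intervals, and those below, were computed within each mutant library, so they do not measure the spread between libraries. A constant background of reads per piRNA predicted 14.6% and 3.58% kept in the middle group, against 21.9% and 5.27% observed, an excess of 3.39 to 11.2 and of 0.470 to 2.88 percentage points (95% bootstrap intervals), which argues against it as the whole cause, by a small margin in mutant replicate 2. A background that differs between piRNAs, or a biological difference in how abundant piRNAs are held, may contribute and was not tested.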
